A study of Mus musculus with 12 samples.

How the data were processed

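Bulk RNA of mouse sciatic nerve was measured in 12 libraries, 3 in each of 4 groups (control and dKO, intact and 5 days after transection). Per the labels, libraries were made from polyA RNA with an Ion Torrent total RNA kit, and the authors used DESeq2 with R 4.2.1 on reads mapped to mm10. The aligner, the counting tool, the strand and the annotation release are not given in the sources used here. The deposited raw table holds counts of reads per gene model, as whole numbers. The deposited normalized table holds a signal, the raw counts divided by 1 size factor per library by the authors with DESeq2: the ratio of both tables was constant within a library to 0.47%. Gene models are named by symbol alone. Of 38087 gene models, 278 symbols stood on several lines and 25 names looked like dates written by a spreadsheet; 28 models with a mean count of 50 or more were identical to another in every library and held 0.199% of all counts. Positions came from GENCODE M21 by symbol, older symbols through 14 aliases; 87% of the tested models matched a single gene.

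Counts were tested with edgeR 4.0.16 in R 4.3.3: models were kept by filterByExpr over the 4 groups (minimum count 10), which left 22384, with TMM factors, robust quasi-likelihood fits of 1 model with a mean per group over all 12 libraries, and F-tests. Benjamini-Hochberg adjustment was over all tested models within a comparison, with a threshold of 0.05. Every adjusted p of a gene in the text is from edgeR unless another tool is named. The comparisons were injury in control, injury in dKO, genotype in intact nerve, genotype at 5 days, the difference of both injury changes, and their mean. Injury attenuation is the share of genes called in the mean injury change whose change was smaller in dKO, with a 95% exact binomial interval. With 3 libraries against 3 an exact permutation test of a single value cannot go below a p of 0.1, so no such test was used for single genes.

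Gene lists (38, with 739 genes, from textbook knowledge) were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, unless said otherwise. The 33 lists with at least 5 tested members and no use as a check were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. The adjusted p of a list is over the 33 lists. Members are counted as changed at the threshold over all genes, and counts adjusted over the list alone are given beside them. The rule named Tfeb, Tfe3 and Dhh, the 10 largest rises and falls per comparison among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between groups (not required for the difference of injury changes), predicted models left out, and up to 4 members of a list with the smallest p.

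Library totals ran from 15430999 to 35845371 counts. Simulated counts were drawn from the mean and spread of each gene, with 200 genes changed and without a library set or links between genes. In these, genotype comparisons found 13.4% (intact) and 9% (5 days) of changes of 1.5-fold, 50.7% and 44.8% of 2-fold and 72.7% and 68.2% of 4-fold. The difference of injury changes found 0%, 14.9% and 57.6%. False calls made up 4.2% (intact) and 8% (5 days) of the calls between genotypes, and 7.7% of those for the difference. For injury they made up 5.1% in control and 2.6% in dKO nerve. An attenuation share made to be absent came out as 50.1% for rising and 49.6% for falling genes. These draws gave both genotypes the same spread, so they cannot show a bias from unequal spread. Replicates were checked for duplicates, and each pair differed far beyond counting noise. Sex was read from Xist and Y-linked counts. A second library set was found from reads on olfactory receptor genes (over 2 times the median number of such genes at equal depth) after the data were seen. A term for this set was then added to every fit, an alternative chosen after seeing the data. The set effect in that fit is estimated from the control libraries at 5 days, with 1 of them in the second set, and assumes that this library varies like the others.

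Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 and upper-quartile scaling factors, no and a stricter low-count filter (at least 1 CPM in 3 libraries and a mean count of 10), fits of only the compared groups, a minimum log2 change of 1, a threshold of 0.01, sex as a covariate, the authors' normalized values (log2 of the value plus 1) with limma-trend, the replicate numbers as a block, and leaving out each library in turn. Of the 38 lists, 3 served as checks (genes near Tfeb, genes near Tfe3 and sex-linked genes), and lists with fewer than 5 tested members were not tested. Of 31 genes near Tfe3, 8 were lower and 0 higher at 5 days in dKO nerve, with 10 lower and 1 higher adjusted over the list alone. Among all 22384 tested models 2008 were lower and 699 higher in that comparison. Why genes near Tfe3 were lower was not tested. Of 17 genes near Tfeb, 0 passed in edgeR in the same comparison, with 0 adjusted over the list alone. All sample columns were used.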

Results

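RNA of mouse sciatic nerve was sequenced in 4 groups of 3 libraries each. The groups were intact nerve and injured nerve of control mice, and intact nerve and injured nerve of mice called dKO here. By the labels the dKO mice lacked Tfe3 in every cell and lost Tfeb in Schwann cells through a Cre recombinase driven by Dhh, a gene of the Schwann cell lineage. Control mice carried no Cre and kept Tfe3. Injured nerve was the stump beyond a transection, taken 5 days after it, and intact nerve came from the opposite side of injured mice. By the labels the epineurium, the outer sheath with its fibroblasts, fat and vessels, was stripped from intact nerves, and no such step is stated for injured ones. Total counts per library were 29391813, 27735102 and 31052996 in control intact nerve and 29374657, 35845371 and 32706423 in dKO intact nerve. They were 31176640, 30238088 and 21679659 in control nerve at 5 days and 28700008, 30912644 and 15430999 in dKO nerve at 5 days. The tests covered 22384 gene models. Values below are CPM, counts scaled to library size, as mean ± SD with n = 3, and changes are log2 fold changes with their standard error (SE).

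Tfeb and Tfe3 were still read over the whole gene in every dKO library. In control intact nerve Tfeb stood at 22.6, 23.9 and 26.9 CPM, and in dKO intact nerve at 17, 19.5 and 17.3 CPM. At 5 days it stood at 24.0, 18.2 and 18.4 CPM in control and 14.2, 19.6 and 29.7 CPM in dKO. Tfe3 stood at 62.0, 60.8 and 56.6 CPM in control intact nerve and 46.3, 47.3 and 43.3 CPM in dKO intact nerve. At 5 days it stood at 61.6, 67.6 and 54.9 CPM in control and 52.4, 53.8 and 49.5 CPM in dKO. The genotype difference of Tfe3 was -0.39 (SE 0.10, adjusted p = 0.841) in intact nerve and -0.24 (SE 0.10, adjusted p = 0.126) at 5 days. That of Tfeb was -0.45 (SE 0.22, adjusted p = 0.856) and 0.06 (SE 0.22, adjusted p = 0.883). Neither passed the test, and counts over a whole gene cannot show whether an exon was deleted. Tfeb lies on chromosome 17 from 47737030 to 47792419 and Tfe3 on chromosome X from 7762560 to 7775202 (GRCm38, the mm10 build, matched by symbol to GENCODE M21).

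**Figure D1:**
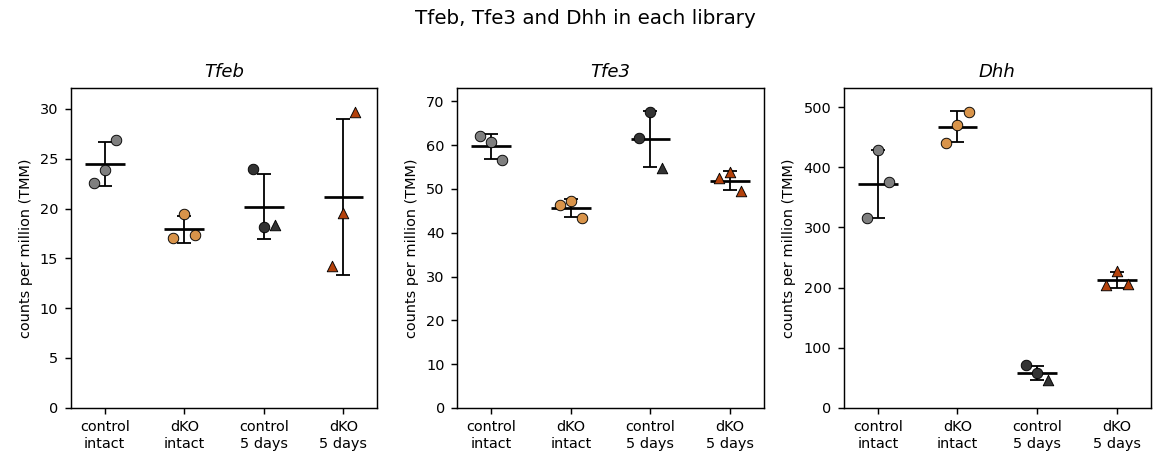
CPM (y axis, TMM scaling, starting at 0) of Tfeb, Tfe3 and Dhh in each library of the 4 groups (x axis). Horizontal lines are group means, error bars are SD (n = 3), and triangles mark the 4 libraries that share an unusual read pattern; Dhh stood at 58.0 CPM in control and 213 CPM in dKO nerve at 5 days.

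The libraries differed in ways that the groups do not explain. Control replicate 1 at 5 days was taken as female, with 10712 counts of Xist and 244 counts of Y-linked genes. Each of the other libraries held at most 23 counts of Xist and between 1907 and 3724 of Y-linked genes. Where the 244 counts came from was not tested. Control replicate 4 and all 3 dKO libraries at 5 days formed a second library set. With every library thinned to the total of the smallest one, between 159 and 337 olfactory receptor genes had a read in these 4 libraries, and between 48 and 66 in the other 8. The gene model Gm2302 had 259 to 351 counts in the second set and 0 to 1 in the first, and AC161763.1 had 2 to 4 counts against 272 to 2479. In total 1289 gene models were higher, and 1307 lower, in all 4 than in all 8. With control replicate 1 in the place of replicate 4 these numbers were 432 and 400, and with replicate 2 they were 373 and 288. Comparisons of genotype at 5 days therefore had 1 control library within the second set, and intact nerve had 0 libraries in it. A term for the set in the model compares control replicate 4 with control replicates 1 and 2 at 5 days, so it has little power for single genes. Since replicate 1 is the female library, the term also takes up part of what sets that library apart. In comparisons that use dKO nerve at 5 days, calls kept or lost with that term rest on that 1 control library. In a principal component analysis the first component (58.9% of the variance) parted intact from injured nerve, and the second (13.6%) ran from -107.5 in the female control library to 52.8 in dKO replicate 2 at 5 days.

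The first comparison asked what transection changed in control nerve. Among the lists tested, genes of cell division rose and genes of myelin fell by the largest medians. Mki67, a marker of dividing cells, went from 1.76 ± 0.223 to 192 ± 23 CPM. Prx, which encodes periaxin of the Schwann cell membrane, went from 6940 ± 770 to 44.7 ± 4.7 CPM. Among single genes the largest rises were those of Gzmb (granzyme B of killer lymphocytes), Pbk (a mitotic kinase), Asgr1, Ccnb1 (cyclin B1), Igfbp2, Gdnf (a neurotrophic factor), Fam64a, BC030867, Cdk1 and Btc, between 7.19 and 13.03. Gzmb was the least certain of these (SE 1.31), since its intact libraries held almost no reads (0.0122 ± 0.0211 CPM) and its injured ones varied (141 ± 109 CPM). The largest falls were those of Ddn, Fgf4, Sec14l5, Plk5, Ncmap (a myelin protein), Spnb5, Fa2h (which makes hydroxylated myelin lipids), Myh6, Tmem229a and Lect1, between -10.7 and -7.55. Prx lies on chromosome 7 from 27499324 to 27520214 and Mki67 on chromosome 7 from 135689784 to 135716361. In total 5452 genes rose and 5022 fell. The 3 injured and 3 intact libraries did not overlap for 53.3% of the genes tested, where chance gives 10%.

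By gene list, all 32 cell division genes rose in control nerve (median 4.54), among them Mki67 (6.76), Ccna2 (4.25) and Rrm2 (6.55). Of 32 myelin genes 29 fell and 1 rose (median -3.30), with Prx at -7.28, Mag at -5.90 and Cldn19 at -6.08. These 2 lists also passed camera with an estimated correlation (adjusted p = 0.00501 and 0.0255). Of 35 repair Schwann cell genes 26 rose and 6 fell (median 2.92), with Clcf1 at 4.57, Tnc at 4.55 and Runx2 at 5.12. Of 24 cholesterol synthesis genes 22 fell and 1 rose (median -2.87), with Fdps at -3.43. Both passed the preset test and had an adjusted p = 0.0537 with an estimated correlation. Of 31 macrophage markers 26 rose and 1 fell (median 2.55; adjusted p = 0.0911 with an estimated correlation), with Lgals3 at 6.14, Arg1 at 4.53 and Trem2 at 3.66. Adjusted over the list alone, the counts that rose or fell were 32 and 0 for cell division, 1 and 29 for myelin, 27 and 6 for repair, 1 and 22 for cholesterol and 27 and 1 for macrophages.

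Among lysosomal genes, known targets of TFEB and TFE3, many enzymes and V-ATPase genes rose in control nerve, and membrane proteins did not pass as a group. Of 39 lysosomal enzymes 24 rose and 10 fell (median 0.68; adjusted p = 0.0658 with an estimated correlation), with Hexa at 1.89, Ctsd at 2.06 and Gusb at 1.70. Of 17 subunits and partners of the V-ATPase, the proton pump of lysosomes, 13 rose and 1 fell (median 0.53; adjusted p = 0.112 with an estimated correlation), with Atp6v0d2 at 6.69 and Atp6v1b2 at 1.57. Of 24 lysosomal membrane proteins 9 rose and 4 fell (median 0.17; adjusted p = 0.419 in the preset test). Of 18 matrix remodelling genes 14 rose and 1 fell (median 1.64; adjusted p = 0.0926 with an estimated correlation), with Timp1 at 4.69 and Mmp19 at 1.97. Of 20 lipid handling genes 9 rose and 6 fell (median 0.37; adjusted p = 0.0911 with an estimated correlation), with Lipa, the lysosomal acid lipase, at 1.90. Of 25 chemokines and cytokines 11 rose and 2 fell (median 1.26; adjusted p = 0.165 with an estimated correlation), with Tgfb1 at 2.93. Fatty acid synthesis genes fell in 11 of 19 cases (median -1.18; adjusted p = 0.0993 with an estimated correlation), with Scd2 at -2.43. Autophagy genes fell in 21 of 44 cases and rose in 3 (median -0.29; adjusted p = 0.386 with an estimated correlation), with Wipi2 at -0.90. With the library set as a term 18 of them fell and 3 rose (median -0.23), and the preset call ended (adjusted p = 0.0748 by camera). Of 12 markers of Schwann cells at large 8 fell and 2 rose (median -0.80; adjusted p = 0.534 with an estimated correlation). Adjusted over the list alone, the counts that rose or fell were 24 and 10 for enzymes, 15 and 1 for the V-ATPase, 14 and 1 for matrix, 9 and 6 for lipid handling, 12 and 2 for chemokines, 0 and 12 for fatty acids, 3 and 22 for autophagy and 2 and 8 for Schwann cells. All 4 red cell genes, too few for a test of the list, rose too (median 5.20), with Hba-a1 at 1450 ± 2220 CPM in injured control nerve. Most of this came from replicate 1, where the list stood 7.06 above the intact mean, against 1.34 and 2.74 in the other injured control libraries.

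The second comparison asked what transection changed in dKO nerve. Genes of cell division rose and genes of myelin fell here too: Mki67 went from 1.43 ± 0.0556 to 69.8 ± 5.44 CPM and Prx from 7330 ± 244 to 331 ± 27.6 CPM. The largest rises were those of Asgr1, Gzmb, Wif1 (an inhibitor of Wnt signalling), Cdk1, Ankle1, Gdnf, Cdca5, Fam64a, Pbk and Ucn2, between 6.58 and 8.96. Among the largest falls were Plk5 (-8.26), Ddn (-8.11), Sec14l5 (-6.42) and Tmem229a (-5.89). The other 6 of the 10 largest falls were the gene models AC161763.1, AC154909.1, AC134325.1, AC105256.2, AC162893.2 and AC091522.1, which were low in every library of the second set, control replicate 4 included. In total 4930 genes rose and 5067 fell, and the libraries did not overlap for 61% of the genes, where chance gives 10%. With upper-quartile scaling the median of all genes shifted by 0.141, and 6246 genes rose and 4044 fell. All 3 injured dKO libraries belonged to the second set and all 3 intact ones to the first. With the set as a term, estimated from the control libraries, 2146 genes rose and 2153 fell, and 4000 of the 9997 calls were kept. Genes that lost their call went from a median absolute change of 0.80 to 0.56, with a median SE of 0.20 and 0.34.

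By gene list, all 32 cell division genes rose in dKO nerve (median 3.39, with Mki67 at 5.61), and 26 of 32 myelin genes fell and 1 rose (median -2.32), with Prx at -4.47, Cldn19 at -3.85 and Dusp15 at -4.71. Of 35 repair Schwann cell genes 28 rose and 6 fell (median 2.10), with Shh at 6.19, Tnc at 4.78 and Clcf1 at 3.53. Of 24 cholesterol synthesis genes 22 fell (median -2.42), with Fdps at -2.99. These 4 lists passed with an estimated correlation too (adjusted p = 0.00489, 0.0293, 0.0365 and 0.0365). Of 31 macrophage markers 26 rose (median 2.25; adjusted p = 0.0867 with an estimated correlation), with Lgals3 at 2.12, Arg1 at 4.44, Mpeg1 at 3.52 and Trem2 at 3.59. Of 39 lysosomal enzymes 18 rose and 9 fell (median 0.28; adjusted p = 0.308 with an estimated correlation), with Hexa at 1.18, Ctsb at 1.61 and Ctsd at 1.32. Of 18 matrix remodelling genes 12 rose and 2 fell (median 1.44; adjusted p = 0.0867 with an estimated correlation), with Timp1 at 5.10. Of 17 V-ATPase genes 7 rose and 2 fell (median 0.11), and the list did not pass the preset test (adjusted p = 0.423). Its members included Atp6v0d2 at 3.01, Atp6v0a1 at -0.96 and Atp6v1b2 at 0.54. Nor did lysosomal membrane proteins, of which 3 rose and 11 fell (median -0.23, adjusted p = 0.0615), and lipid handling genes, of which 5 rose and 5 fell (median 0.05, adjusted p = 0.671). Schwann cell markers fell in 10 of 12 cases (median -1.14), fatty acid synthesis genes in 10 of 19 (median -0.79) and autophagy genes in 29 of 44, with 2 that rose (median -0.48). Of 25 chemokines and cytokines 14 rose and 1 fell (median 1.46), and of 16 lymphocyte markers 9 rose (median 2.22). The adjusted p of these last 5 lists with an estimated correlation was 0.347, 0.173, 0.173, 0.138 and 0.308. With the set as a term, lysosomal enzymes (9 rose and 2 fell, median 0.30, adjusted p = 0.0553) and lymphocyte markers (1 rose, median 1.96, adjusted p = 0.0636) lost their preset call. Autophagy genes kept it with 10 that fell and 1 that rose (median -0.24). Cell division, myelin and repair genes kept medians of 3.72, -2.03 and 2.36 and passed with an estimated correlation, and cholesterol synthesis genes (median -2.45) had an adjusted p = 0.0516 with an estimated correlation. Adjusted over the list alone, the counts that rose or fell were 32 and 0 for cell division, 1 and 26 for myelin, 28 and 6 for repair, 0 and 22 for cholesterol, 26 and 0 for macrophages, 20 and 9 for enzymes, 13 and 2 for matrix and 7 and 2 for the V-ATPase.

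Many genes of the injury response were shared between genotypes. Of the 5452 genes that rose in control nerve 3543 also rose in dKO nerve, where chance gives 1201. Of the 5022 that fell 3950 also fell in dKO nerve, where chance gives 1137, and 46 genes went opposite ways. Markers of other cells of the nerve moved both ways with injury. Of 21 fibroblast markers 7 rose and 5 fell in control and 9 rose and 3 fell in dKO nerve, and of 16 endothelial markers 1 rose in each and 7 and 6 fell. Fibroblast markers had a median change of 0.30 in control and 0.59 in dKO nerve, perineurial markers -0.11 and -0.13, endothelial markers -0.32 and -0.08, vessel wall markers -0.24 and 0.18 and fat cell markers 0.75 and 0.51. Muscle markers had a median of -0.88 and 1.25, of which each rested on a library: they were 0.08 without control intact replicate 1 and 0.38 without dKO replicate 4 at 5 days. These 6 lists did not pass camera in either genotype, while fry passed for endothelial markers in control (adjusted p = 0.0356) and fibroblast markers in dKO nerve (adjusted p = 0.0207), and intact nerve had lost its epineurium by the labels.

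The third comparison asked how the genotypes differed in intact nerve. A single gene passed the test with edgeR: Cthrc1, a secreted matrix protein, at 4.24 ± 0.929 CPM in control and 1.48 ± 0.373 CPM in dKO nerve (-1.53, SE 0.20, adjusted p = 0.0458). Shh followed at 9.33 ± 2.81 and 3.36 ± 0.879 CPM (-1.47, SE 0.21, adjusted p = 0.057). In edgeR 0 genes were higher in dKO nerve. At an unadjusted p under 0.05 edgeR listed 1299 of the 22384 tested genes, little more than the share of 0.05 that chance gives. At the adjusted threshold DESeq2 called 5 higher and 7 lower, and limma-voom called 0. The call of Cthrc1 held without control replicate 1 (adjusted p = 0.0257) and was lost without any other of the compared libraries (adjusted p = 0.0513 to 0.257). Without control replicate 2, dKO replicate 2 or dKO replicate 3 in turn 0 genes passed in edgeR, and without control replicates 1 or 3 or dKO replicate 4 in turn 2 passed. The groups did not overlap for 14.6% of the genes, where chance gives 10%. Cthrc1 lies on chromosome 15 from 39076932 to 39087121.

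In intact nerve myelin genes (median -0.03), repair genes (median -0.08) and macrophage markers (median 0.15) had 0 of their members past the threshold in edgeR. Cholesterol synthesis genes were lower as a group in the preset test (median -0.39; adjusted p = 0.317 with an estimated correlation), and 7 of 24 passed when adjusted over the list alone; Sqle stood at 216 ± 37 and 150 ± 12.1 CPM. Mast cell markers were higher as a group (median 0.82; adjusted p = 0.178 with an estimated correlation), with 4 of 9 past the threshold adjusted over the list alone. Feedback and marker genes of the TFEB and TFE3 family had a median of -0.16 (adjusted p = 0.168 with an estimated correlation), with Gpnmb at 54.8 ± 2.32 and 27.1 ± 6.75 CPM, and were the 1 list that passed fry. The preset test also listed lysosomal enzymes (-0.05), V-ATPase genes (-0.13), cell division genes (-0.11) and interferon genes (-0.24) as lower. It listed perineurial (0.38), endothelial (0.26), fat cell (0.42) and immediate early genes (0.50) as higher. None of these lists passed with an estimated correlation, where adjusted p ranged from 0.168 for the feedback genes to 0.634 for the cell division, interferon, perineurial and fat cell lists.

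The fourth comparison asked how the genotypes differed 5 days after transection. In dKO nerve several myelin genes stayed above, and genes of cell division and the lysosome below, their levels in control nerve. Mag stood at 6.69 ± 1.18 CPM in control and 54.4 ± 5.74 CPM in dKO nerve (3.03, SE 0.14), and Pmp2, a myelin lipid carrier, at 74.4 ± 7.56 and 557 ± 56.7 CPM (2.91, SE 0.19). Lgals3, which encodes galectin-3, stood at 2210 ± 170 CPM in control and 151 ± 10.7 CPM in dKO nerve (-3.88, SE 0.11). Atp6v0d2, a V-ATPase subunit, stood at 74.9 ± 5.58 and 4.80 ± 1.77 CPM (-3.96, SE 0.30), and Hmga2, a chromatin protein, at 179 ± 50.7 and 11.1 ± 2.14 CPM (-4.01, SE 0.26). In intact nerve these genes stood at like levels in both genotypes, as Lgals3 at 31.3 ± 0.315 and 34.7 ± 2.22 CPM.

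Other large rises in dKO nerve at 5 days were those of Fgf4 (4.31), Myh6 (4.29), Spnb5 (3.72), Ncmap (3.55), Nptx2 (3.31), Lrtm2 (2.99), AC116720.1 (2.95) and Cdsn (2.92). Fgf4 held almost no reads in control nerve at 5 days (0.0411 ± 0.0711 CPM; SE of the change 0.75). Nptx2, a neuronal pentraxin, stood at 4.13 ± 0.802 and 40.9 ± 1.91 CPM. Other large falls were those of Foxq1, a forkhead transcription factor (-4.88), and Eef1a2, an elongation factor (-4.56). The other 5 of the 10 largest falls, AC134325.1, AC154909.1, AC105256.2, AC091522.1 and AC162893.2, were low in control replicate 4 as well. Mag lies on chromosome 7 from 30899176 to 30914873, Pmp2 on chromosome 3 from 10179851 to 10183929 and Lgals3 on chromosome 14 from 47367751 to 47386160. Atp6v0d2 lies on chromosome 4 from 19876841 to 19922605 and Hmga2 on chromosome 10 from 120361275 to 120476469. In total 699 genes were higher and 2008 lower in dKO nerve, and the groups did not overlap for 30.5% of the genes, where chance gives 10%. Of the 2008 lower genes 59% rose on injury in the mean of both genotypes, and of the 699 higher ones 63.9% fell. Among genes without a genotype call 29% rose and 27.8% fell. Both sorts of call use the same libraries at 5 days. With equal group sizes their estimates share no chance error only if both genotypes vary alike, which was not tested. When the library set was a term of the model, 145 genes were higher and 370 lower, and 499 of the 2707 calls were kept. The 2208 others went from a median absolute change of 0.65 to 0.50, with a median SE of 0.15 and 0.20. Of the 20 genes with the largest changes 14 kept their call, and the 6 that lost it were Fgf4 and the 5 AC models. Without control replicate 4 at 5 days 4225 genes passed, without control replicate 1 1714, and without dKO replicates 2 or 3 at 5 days 1692 and 1577. With upper-quartile scaling the median change of all genes shifted by 0.108, and 1075 genes were higher and 1345 lower.

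**Figure D2:**
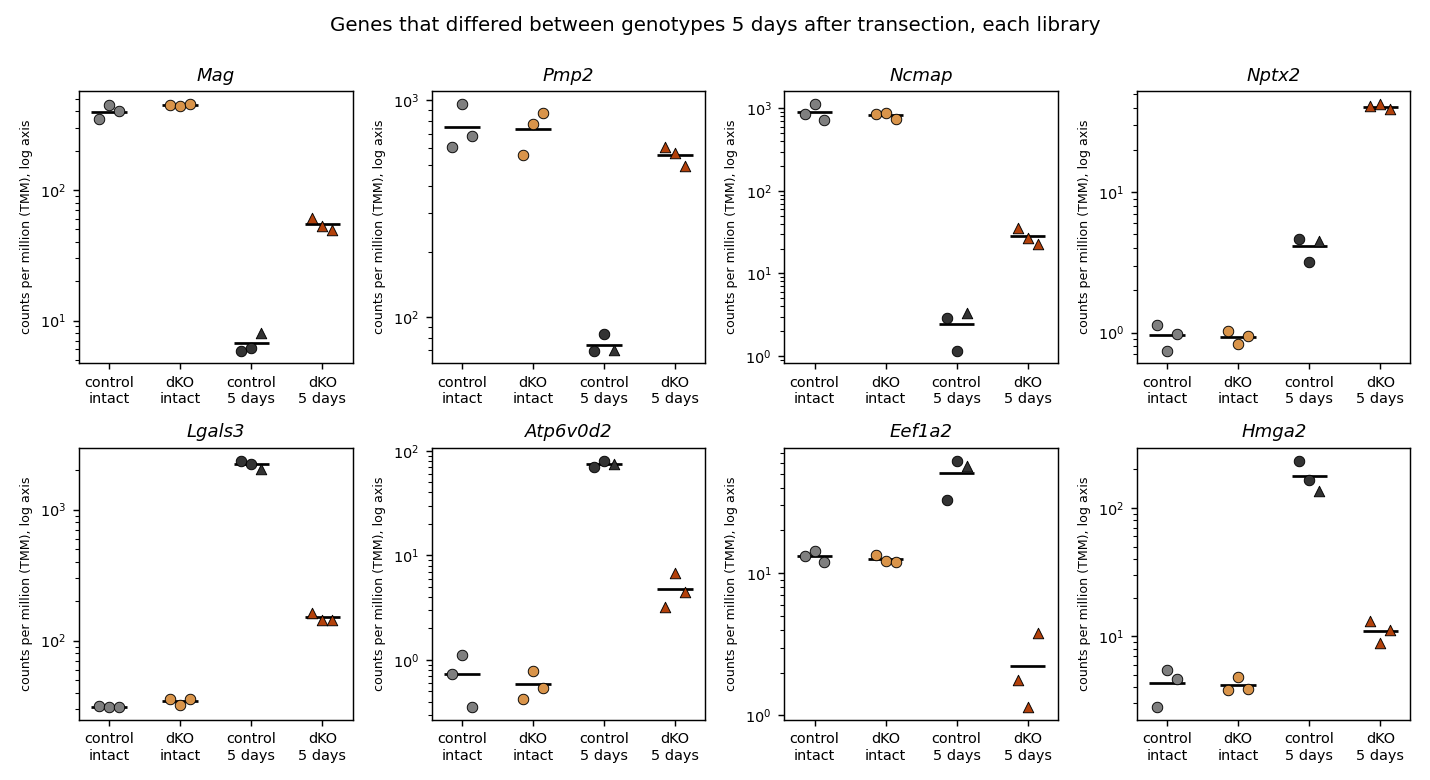
CPM (y axis, TMM scaling, log axis) of 8 genes with large differences between genotypes at 5 days, in each library of the 4 groups (x axis). Horizontal lines are group means (n = 3) and triangles mark the second library set. The genes were chosen without overlap between genotypes at 5 days, so control replicate 4, the triangle among the control libraries at 5 days, lies on the control side by that choice. AC models among the largest falls, low in control replicate 4 as well, are not drawn. Lgals3 had a control mean of 2210 CPM and a dKO mean of 151 CPM.

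By gene list, 18 of 32 myelin genes were higher and 5 lower in dKO nerve at 5 days (median 0.92; adjusted p = 0.0383 with an estimated correlation), with Prx at 2.89, Mag at 3.03, Pmp2 at 2.91 and Cldn19 at 2.27. Cell division genes were lower in 31 of 32 cases (median -1.34; adjusted p = 0.00584 with an estimated correlation), with Mki67 at -1.46, Nusap1 at -1.42, Rrm2 at -1.80 and Ccna2 at -1.31. V-ATPase genes were lower in 16 of 17 cases (median -0.60; adjusted p = 0.00584 with an estimated correlation), with Atp6v1b2 at -1.08, Atp6v0c at -0.81 and Atp6v0b at -0.82. Lysosomal membrane proteins were lower in 17 of 24 cases (median -0.56; adjusted p = 0.00584 with an estimated correlation), with Abcb9 at -1.33, Scarb2 at -1.37, Npc1 at -1.14 and Mcoln1 at -0.62. Lysosomal enzymes were lower in 16 of 39 cases (median -0.31; adjusted p = 0.0147 with an estimated correlation), with Lipa at -1.80, Psap (prosaposin) at -1.79, Tpp1 at -0.98 and Gla at -1.89. Lipid handling genes were lower in 10 of 20 cases and higher in 2 (median -0.38; adjusted p = 0.00584 with an estimated correlation), with Nceh1 at -1.69, Fabp5 at -1.20 and the cholesterol exporter Abca1 at -1.39. Of the feedback and marker genes of the TFEB and TFE3 family 5 of 14 were lower (median -0.39; adjusted p = 0.0218 with an estimated correlation), with Gpnmb at -3.05, Fnip1 at -1.09, Flcn at -0.60 and Rragd at -1.40. Adjusted over the list alone, the counts higher and lower were 21 and 6 for myelin, 0 and 32 for cell division, 0 and 17 for the V-ATPase, 1 and 18 for membrane proteins, 2 and 17 for enzymes, 2 and 10 for lipid handling and 0 and 7 for feedback genes. Under the model with the library set, 16 myelin genes stayed higher, and 12 cell division, 8 membrane, 10 enzyme and 8 lipid handling genes were lower; medians were 0.95, -1.07, -0.50, -0.40 and -0.47. In that fit 6 V-ATPase genes were lower (median -0.47), and among the feedback genes (median -0.50) the call of Gpnmb remained (-3.23) while those of Fnip1 (-0.67, SE 0.22), Flcn (-0.71, SE 0.17) and Rragd (-1.09, SE 0.43) were lost. In that fit the dKO libraries at 5 days are set against control replicate 4 alone, so its medians and calls rest on 1 control library.

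**Figure D3:**
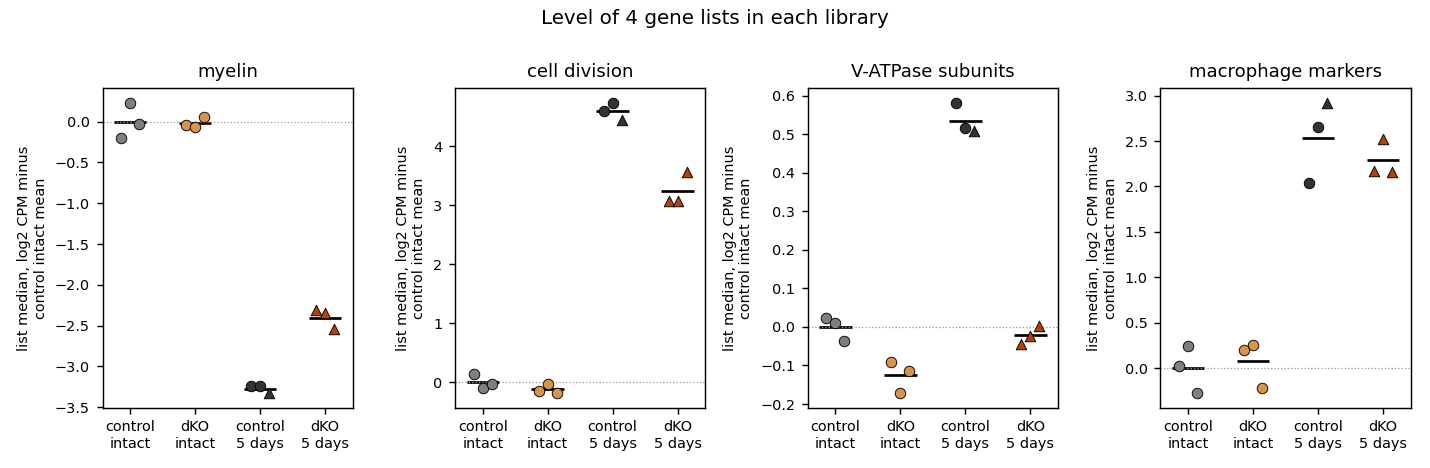
Median log2 CPM of 4 gene lists relative to the mean of control intact nerve (y axis) in each library of the 4 groups (x axis). Horizontal lines are group means (n = 3) and triangles mark the second library set. The median fold change of the members between genotypes at 5 days, which is not the distance drawn, was 0.92 for myelin, -1.34 for cell division and -0.60 for the V-ATPase. It was -0.06 for the macrophage list, which did not pass the test. The macrophage levels drawn at 5 days were 2.04, 2.65 and 2.92 in control and 2.175, 2.525 and 2.164 in dKO nerve.

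Repair Schwann cell genes were lower in 16 of 35 cases and higher in 2 in dKO nerve at 5 days (median -0.65; 17 lower and 5 higher adjusted over the list alone), a group call that was lost with an estimated correlation (adjusted p = 0.163). In the fit with the library set as a term 7 were lower and 2 higher (median -0.32). Ngfr, the low-affinity neurotrophin receptor, stood at 1630 ± 298 CPM in control and 514 ± 62.7 CPM in dKO nerve, Sox2 at 141 ± 29.3 and 59.1 ± 3.49 CPM and Runx2 at 201 ± 50.2 and 76.9 ± 13.1 CPM. Schwann cell markers at large moved apart: 6 of 12 were lower, among them Cdh19 (-1.41), Foxd3 (-1.25) and S100b (-1.42), and Egfl8 was higher (2.51; median of the list -0.54; adjusted p = 0.602 with an estimated correlation). The library set as a term ended the preset call of this list (median -0.21, 4 lower, adjusted p = 0.312). Dhh itself was higher in dKO nerve, at 58.0 ± 12.1 and 213 ± 13.4 CPM (1.88, SE 0.15). In intact nerve it stood at 315, 428 and 375 CPM in control and 441, 470 and 492 CPM in dKO. Control mice carried no Cre, and whether the Cre driven by Dhh added reads to this gene in dKO mice was not tested. Genes of the integrated stress response were higher in 7 of 23 cases and lower in 1 (median 0.23; adjusted p = 0.0875 with an estimated correlation), with Phgdh at 0.83, Slc7a5 at 1.28, Asns at 0.91 and Ddit3 at 0.82. Autophagy genes were lower in 8 of 44 cases (median -0.11, about the size of the shift by upper-quartile scaling; adjusted p = 0.441 with an estimated correlation), with Sqstm1 at -0.61. In edgeR with the library set as a term 0 of them were lower (median -0.03), and the preset call ended (adjusted p = 0.366). With the library set as a term the calls of Slc7a5 (1.56, SE 0.36), Asns (1.04, SE 0.28), Ddit3 (0.73, SE 0.25) and Sqstm1 (-0.52, SE 0.16) were lost, with larger SE than the 0.24, 0.19, 0.17 and 0.11 without it. The stress list then had a median of 0.16 and passed the preset test (adjusted p = 0.0101) but not with an estimated correlation (adjusted p = 0.122).

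Markers of other cell types were mixed at 5 days. Of 31 macrophage markers 2 were lower, Lgals3 and Cd68 (-0.87), and 1 was higher, Cd14 (0.73); the list median was -0.06 and the list did not pass (adjusted p = 0.0964). Its median was -0.28 with the library set as a term, with 1 member lower; the list then passed the preset test (adjusted p = 5.8e-06), a call lost with an estimated correlation (adjusted p = 0.434). Fibroblast markers were higher in 4 of 21 cases (median 0.46; adjusted p = 0.38 with an estimated correlation), with Col1a1 at 0.56 and Tnxb at 0.63, and endothelial markers in 3 of 16 (median 0.53; adjusted p = 0.441 with an estimated correlation), with Vwf at 0.75. In edgeR 0 fibroblast and 0 endothelial genes passed with the library set as a term, with medians of 0.29 and 0.47. Vessel wall (median 0.74) and muscle markers (median 1.37) passed the preset test with 0 members past the threshold (adjusted p = 0.602 for both with an estimated correlation). The muscle value came from dKO replicate 4, and without it the median was 0.41 and the list did not pass (adjusted p = 0.159). With the library set as a term the medians were 0.78 for vessel wall and 0.72 for muscle markers, and both preset calls ended. Perineurial (0.46), fat cell (0.34), lymphocyte (-0.26), neutrophil (-0.01), mast cell (-0.13) and neuronal lists (0.76) did not pass. Nor did the lists of nonmyelinating Schwann cells (-0.07), cholesterol (-0.06) and fatty acid synthesis (0.12), chemokines (0.11), interferon genes (-0.11), immediate early genes (0.14), glycolysis (-0.15), respiratory chain (-0.09), matrix remodelling (-0.02), phagocytosis receptors (-0.10) and neurotrophin signalling (0.25).

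The fifth comparison asked for which genes the injury change itself differed between genotypes. Genes that fell on injury in control nerve fell less in dKO nerve at Mag (2.86, SE 0.19), Pmp2 (2.94, SE 0.26) and Prx (2.81, SE 0.17). Genes that rose on injury in control nerve rose less at Lgals3 (-4.02, SE 0.15), Atp6v0d2 (-3.68, SE 0.51) and Igfbp2 (-3.38, SE 0.66). In total the injury change was higher in dKO nerve for 165 genes and lower for 485. Other large positive differences were those of Myh6 (4.50), Fgf4 (4.30), Spnb5 (4.05), Ncmap (3.68), Nptx2 (3.35), Cdh1 (E-cadherin, 3.25), AC116720.1 (3.17) and Lrtm2 (3.13). Other large negative ones were those of Foxq1 (-5.09), Eef1a2 (-4.50), Hmga2 (-3.97), Fgfbp3 (-2.93), Pbk (-2.74), Gadd45b (-2.67) and Dusp10 (-2.55). With the library set as a term 75 genes were higher and 97 lower, and 167 of the 650 calls were kept; Fgf4, Lrtm2 and Igfbp2 lost theirs among the 20 largest. The 483 that were lost went from a median absolute change of 1.00 to 0.85, with a median SE of 0.21 and 0.24. Without control replicate 4 at 5 days 1276 genes passed, and without dKO replicate 3 at 5 days 352. Counts were also over 1.5 times lower without control intact replicate 3 (419) and dKO intact replicates 2 (379) and 4 (426). With DESeq2 1096 genes passed, and with upper-quartile scaling the median of all genes shifted by 0.128 and 224 genes were higher and 296 lower.

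Of the 33 lists 5 passed the test of the injury difference with an estimated correlation. Myelin genes were higher in 17 of 32 cases and lower in 1 (median 0.99, adjusted p = 0.0362), and cell division genes were lower in 11 of 32 (median -1.08, adjusted p = 0.0179), with Nusap1 at -1.62 and Mki67 at -1.15. V-ATPase genes were lower in 5 of 17 cases (median -0.48), lysosomal membrane proteins in 6 of 24 (median -0.47) and lipid handling genes in 5 of 20 (median -0.16, close to the shift by upper-quartile scaling), each with an adjusted p = 0.0179. Adjusted over the list alone, the counts higher and lower were 19 and 4 for myelin, 0 and 27 for cell division, 0 and 14 for the V-ATPase, 0 and 15 for membrane proteins and 1 and 9 for lipid handling. Lysosomal enzymes (median -0.25, 8 of 39 lower) and phagocytosis receptors (median -0.24, 1 of 17 lower) passed the preset test and had an adjusted p = 0.0603 and 0.0751 with an estimated correlation (0.0414 and 0.0905 with the library set as a term). So did repair genes (median -0.48, adjusted p = 0.353 with an estimated correlation), where 9 of 35 were lower and 2 higher. Under the model with the library set 13 myelin, 3 cell division, 4 V-ATPase, 1 membrane and 2 lipid handling genes passed in the direction of their list. The list medians were then 1.02, -0.87, -0.41, -0.33 and -0.27, and they rest on control replicate 4 as the only control library at 5 days in the set of the injured dKO libraries. Repair genes lost their preset call in that fit (median -0.25, adjusted p = 0.0512), with 1 lower and 1 higher.

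Across all genes that changed on injury in the mean of both genotypes, 6996 rose and 6304 fell. The change was smaller in dKO nerve for 63.4% of the rising genes (95% interval 62.3% to 64.5%, counting error only) and for 54.2% of the falling ones (52.9% to 55.4%). The median ratio of the dKO change to the control change was 0.818 and 0.946. Genes are not independent, so these intervals do not give the error between mice, which the closing section sets against other splits of the libraries. Chance gives an even share only if both genotypes vary alike, and control libraries at 5 days spread wider on the second principal component. Taken one at a time, 356 rising genes rose less in dKO nerve and 19 rose more, and 135 falling genes fell less and 66 fell more. With the library set as a term 8436 genes changed on injury in the mean of both genotypes.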

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

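Of the tests here, those of other splits of the libraries were set down before their results were seen; those of the library set, the female library, macrophages, Schwann cells and admixture were chosen after the result was seen. A first version of the Schwann cell test, V-ATPase level minus myelin level (-1.51, SE 0.13), was replaced because myelin genes are themselves regulated by injury. The fibroblast test put in its place, a stricter macrophage test and the counts of kept genes for the library set in V-ATPase, myelin and cell division genes were all chosen with list levels in view.

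The injury change differed between genotypes for 650 genes, by a test of the difference itself. In 5 of 100 splits that regrouped genotypes within intact and injured nerve, out of 200 possible, as many genes passed, the real one included, so chance cannot be excluded by this test. The highest other split gave 1355 genes. All 5 kept the real grouping at 5 days and differed in the intact libraries, and with another grouping at 5 days the highest count was 1. For the 13 lists, 29 of 100 splits gave as many (highest other 21), so this number is not beyond chance. Without control intact replicate 2 it was 21 as well.

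The 13 lists had these medians of the difference: myelin 0.99, cholesterol synthesis 0.26, fibroblast 0.49 and muscle 2.12 on the positive side, and repair Schwann cell -0.48, lysosomal enzyme -0.25, lysosomal membrane -0.47, V-ATPase -0.48, macrophage -0.10, mast cell -0.97, cell division -1.08, lipid handling -0.16 and phagocytosis receptor -0.24 on the negative side. The muscle median was 1.26 without dKO replicate 4 at 5 days and 1.41 without control intact replicate 1, and the list then did not pass (adjusted p = 0.0609 and 0.0837). The macrophage median is smaller than the 0.128 by which upper-quartile scaling moves all genes; with the library set as a term it was -0.51 (adjusted p = 0.34 with an estimated correlation). With an estimated correlation the cholesterol, fibroblast, muscle, macrophage and mast cell calls were lost (adjusted p = 0.649, 0.4, 0.544, 0.691 and 0.353). With the library set as a term the mast cell list (median -1.44) and the lysosomal enzyme list (median -0.33) had an adjusted p = 0.0414 each with an estimated correlation, with 0 mast cell genes past the threshold in edgeR.

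Single genes whose injury change differed, with the injury effect tested between genotypes, were on the negative side Foxq1 (-5.09), Eef1a2 (-4.50), Lgals3 (-4.02), Hmga2 (-3.97), Atp6v0d2 (-3.68), Igfbp2 (-3.38), Fgfbp3 (-2.93), Pbk (-2.74), Gadd45b (-2.67), Dusp10 (-2.55), Lipa (-1.75), Rrm2 (-1.69), Abca1 (-1.52), Mki67 (-1.15), Clcf1 (-1.03), Atp6v1b2 (-1.03), Tgfb1 (-0.98), Ctsd (-0.74), Hexa (-0.71) and Gusb (-0.56). On the positive side they were Dusp15 (1.00), Shh (1.13), Dhh (1.55), Cldn19 (2.23), Lect1 (2.41), Ddn (2.59), Fa2h (2.71), Prx (2.81), Mag (2.86), Pmp2 (2.94), Lrtm2 (3.13), AC116720.1 (3.17), Cdh1 (3.25), Nptx2 (3.35), Ncmap (3.68), Spnb5 (4.05), Fgf4 (4.30) and Myh6 (4.50).

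The first pattern weighed is the 2707 genes that differed between genotypes at 5 days, for which the library set, the female control library and the genotype are candidate explanations. With the set as a term 499 genes kept their call and direction, which argues against the set as the whole cause for these, on the assumption that the lone control library of the set varies like the others. The other 2208 lost it: their median absolute change went from 0.65 to 0.50 (median ratio 0.76) while the median SE went from 0.15 to 0.20, so for these the set and the genotype cannot be told apart, since 1 control library carries the estimate. With sex as a covariate 1588 genes kept their call, which argues against the female library as the whole cause for these, and the rest stays open. The set and sex were not fitted together. The estimate of the set also rests on the female library, which had the highest level of red cell genes, so it mixes the set with what sets that library apart. The 10 splits of 3 against 3 are too few for a share under 0.05. The real split gave 2707 genes and 15 lists, and 1 of 10 splits reached each (highest others 8 and 14). The median of the other splits was 0 genes but 12 lists, so the number of lists past the preset test hardly sets the real split apart.

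The second pattern weighed is the lower V-ATPase genes in dKO nerve at 5 days. A loss of lysosomal gene expression in Schwann cells, which by the labels lack both factors, is a hypothesis that was not tested directly. Fewer macrophages, fewer Schwann cells and the library set are technical or compositional candidates. The V-ATPase list fell further than the macrophage list, by -0.51 (SE 0.25), but control replicate 4 alone exceeded the dKO mean in this measure by only 0.17, with an SD of 0.27 among dKO libraries, so by these values fewer macrophages cannot be told apart from a change in Schwann cells; with the set as a term the medians were -0.47 for the V-ATPase and -0.28 for macrophages, the latter not past camera with an estimated correlation (adjusted p = 0.434). Fewer Schwann cells alone would raise markers of other cells alike, and fibroblast and macrophage lists moved apart by 0.53 (SE 0.13), although fibroblast, endothelial and vessel wall medians were all positive; a joint loss of both cell types stays open. With the set as a term 6 of 16 V-ATPase genes kept their call, which argues against the set as the whole cause for those 6, and the other 10 went from a median of -0.54 to -0.44 while their median SE went from 0.11 to 0.14, so the set is not excluded for these. By the labels Tfe3 is knocked out in macrophages too, so a direct effect in them also stays open, untested.

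The last pattern weighed is the smaller injury change of myelin and cell division genes in dKO nerve. An admixture of intact nerve in the dKO samples may lower both changes, but it would need the same share of intact-like RNA for each, and the cell division list needed 63.2% (SD 4.8) and the myelin list 3.6% (SD 0.7), a gap of 59.6 percentage points (SE 2.4). With the library set as a term 12 of 31 cell division genes and 16 of 18 myelin genes kept their genotype call at 5 days, which argues against the set as the whole cause for these. The other 19 cell division genes went from a median of -1.32 to -0.99 while their median SE went from 0.24 to 0.32, so their calls ended with most of the fold left. With 1 control library in the set, neither the set nor a chance difference between mice is excluded for them. In the injury difference itself the list medians went with the term from 0.99 to 1.02 (myelin) and from -1.08 to -0.87 (cell division). Most cell division genes called there lost their call, so for these the set stays open.

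For the remaining results the splits were these. In control injury 1 of 10 splits reached 10474 genes (highest other 0), and 5 reached 13 lists (highest other 16). In dKO injury 1 of 10 reached 9997 genes (highest other 0) and 9 reached 12 lists (highest other 17). In intact nerve 1 of 10 reached 1 gene (highest other 0) and 6 reached 11 lists (highest other 18). With 10 splits a share under 0.05 cannot be had. The other splits of these comparisons gave a median of 12, 15 and 11 lists in this order, about as many as the real ones. The mean injury change gave 13300 genes in 1 of 100 splits, the real one (highest other 3625), so a chance split is an unlikely source of this count. The splits do not part injury from the epineurium step or from the library set. A share of smaller changes as far from even as 63.4% for rising genes was reached by 20 of 100 splits (furthest other 29.8%). One as far as 54.2% for falling genes was reached by 62 (furthest other 28.9%), so chance is not excluded for either. Splits that kept the real grouping at 5 days, or swapped it whole, carry the genotype difference at 5 days. With these among the splits a share under 0.05 could hardly be had, so this test has little power for attenuation.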

How the results depend on the processing

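Here the fits with the library set as a term were chosen after the result was seen, and the other alternatives before. Where a value moved the cause was not tested, except that thresholds and smaller groups act by construction. Counts of genes kept within 1.5 times of their value unless listed. A minimum log2 change of 1 gave 5249 (injury in control), 4918 (injury in dKO), 816 (genotype at 5 days), 378 (difference of injury changes) and 5834 genes (mean injury change), and a threshold of 0.01 gave 1243 for genotype at 5 days and 258 for the difference. DESeq2 gave 1096 for the difference. Sex as a covariate gave 1731 for genotype at 5 days. The library set as a term gave 4299 (injury in dKO), 515 (genotype at 5 days), 172 (difference) and 8436 (mean). For genotype in intact nerve, where edgeR called 1 gene, DESeq2 called 12, both other scalings 2, no filter 5, limma-trend 3 and the set term 3; limma-voom, the strict filter, the sex covariate, the 2 compared groups alone and the threshold of 0.01 called 0. The replicate block gave 290 for the difference and an attenuation of 71.8% for rising genes, with libraries of 1 genotype and number taken as 1 animal. For the comparisons of genotype the block was the replicate number alone, across genotypes and so across mice. It gave 1386 for genotype at 5 days and 0 for genotype in intact nerve. The numbers were not taken as pairs in the main fit. Control 1 looks male in intact and female in injured nerve, and same-numbered libraries of a genotype correlated at -0.09 to 0.12 around their group means. The libraries of dKO 2 and 3 correlated best with their own number and the others did not, so whether some numbers pair stays open. Attenuation of rising genes was 60.6% with DESeq2 factors, 60.4% with DESeq2, 68.1% at the threshold of 0.01 and 55.3% at a mean change of at least 1; that of falling genes was 59.1% with DESeq2 factors, 59.0% with DESeq2, 68.7% at a mean change of at least 1 and 60.4% with the set term. Leaving out each library gave 9193 to 10064 genes for injury in control, 8114 to 8933 for injury in dKO, 0 to 2 for genotype in intact nerve, 1577 to 4225 for genotype at 5 days, 352 to 1276 for the difference and 12325 to 13686 for the mean. It gave attenuation of 59.4% to 67.8% and 51.5% to 63.2%, and 12 to 16, 11 to 15, 9 to 14, 14 to 15 and 13 to 21 lists for the 5 comparisons. Lists past camera numbered 2, 4, 0, 7 and 5 with an estimated correlation and 24, 22 and 1 with fry for both injury comparisons and intact genotype. Among lists past camera with or without an alternative, the direction given by camera changed in 3 cases. These were fat cell genes in intact genotype without control intact replicate 2 (leave-one-out range of the median -0.07 to 1.02), interferon genes without control intact replicate 3 (range -0.43 to 0.07) and macrophage markers in the difference with the replicate block (median 0.19). Changes of sign of the median alone were not counted among such lists. Medians of further lists, not past camera in either fit, also changed sign, as for neutrophil (-0.07) and mast cell markers (-0.57) in dKO injury with the set term. Of 804 named gene results 703 kept their side of the threshold with the set term and 101 lost it; with DESeq2 759 kept it, 41 gained a call and 4 lost it. A 1.5-fold genotype change at 5 days was found in 9% of simulated cases with 200 changed genes; where many more genes change, as at 5 days, the adjusted threshold is less strict.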

Other observations

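The camera test of the neurotrophin list was planned; the tests with the library set as a term were chosen after the result was seen, and the genes named were singled out by their values. Trophic genes moved both ways between genotypes at 5 days: Gdnf stood at 140 ± 31.9 CPM in control and 47.8 ± 6.32 CPM in dKO nerve, its receptor Gfra1 at 756 ± 94.2 and 382 ± 26.4 CPM, and Fgf1 at 32.2 ± 6.26 and 91.5 ± 12.8 CPM. Of 20 genes of neurotrophin signalling 6 were higher and 3 lower (median 0.25, 9 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.189). Gdnf lost its call with the library set as a term (-1.23, SE 0.29), and Gfra1 (-0.77) and Fgf1 (1.49) kept theirs. Megf10, an engulfment receptor, stood at 96.0 ± 6.17 CPM in control and 31.4 ± 4.09 CPM in dKO nerve and kept its call with that term (-1.50).

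Red cell genes varied widely among control libraries at 5 days, with Alas2 at 81.8 ± 123 CPM against 19.8 ± 13 CPM in dKO nerve. Mitf, a relative of Tfeb and Tfe3, stood between 28.8 and 39.6 CPM in all 12 libraries, and Tfec between 0.585 and 4.06 CPM.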
